A study of Teleopsis quinqueguttata with 3 samples.

How the data were processed

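Female and male genomic DNA of Teleopsis quinqueguttata was measured on 3 two-colour Agilent arrays of 1 design. Per the labels' protocols, DNA was extracted from bodies without eyes and digestive tract, treated with RNase and digested for 2 h at 37 °C with the restriction enzymes AluI and RsaI, and 3 µg per sample was labelled with Cy3 or Cy5. Per the labels, the arrays are biological replicates of pools of 4 or 5 flies. The spread between arrays is therefore that between pairs of pools, together with array and dye differences. All 3 arrays lie on 1 slide and carry 1 scan time, per the file headers, so no slide or scan batch was available to test, and the dye orientation was the only technical difference given.

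The scanner files hold spot intensities made by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited processed intensities had a fitted spatial background surface subtracted, a multiplicative detrend applied and a linear dye normalization, per the file headers; the background used for a spot equalled the spatial surface for every probe spot. The deposited log10 ratio column is red (Cy5) over green (Cy3), per the file headers, and equalled the log10 ratio of the processed intensities with a median gap of at most 4.92e-08. The authors also deposited a value table, which was read as log2 ratios made from the scanner ratios by adding a constant per array. Set against the scanner values, its columns had slopes of 1.00, 0.999 and 1.00 on log2 female over male, with offsets of 0.050, 0.050 and 0.10 for replicates 1, 3 and 4, so scale and direction were settled by this comparison. Its column medians were 0.025, 0.029 and 0.051, and how it was centred stays unknown. The value table lists 65522 of the 75082 probes, the first part of the list in alphabetical order, so 9560 probes have scanner values only. No per-sample column was left unmapped.

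From the processed intensities, the log2 ratio of each spot was turned to female over male by the dyes in the labels. Control spots were left out, as were spots marked as outliers, 13, 7 and 25 of 150164 probe spots on replicates 1, 3 and 4. The 2 spots of a probe were averaged. A probe was retained if it was well above background in at least 1 channel on every array, which kept 74198 probes (98.8%). Each array was centred on its median; median log2 ratios before centring were -0.03, -0.02 and -0.06. No loess was applied, since many probes could truly differ in one direction. A target's value was the mean over its retained probes, with at least 3 required, which left out 1027 of 14039 targets.

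Ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 3 arrays, 2 residual degrees of freedom) with Benjamini-Hochberg adjustment. At the target level eBayes added 5.74 prior degrees of freedom, so the variance behind a p-value came more from all targets than from the target's own spread. A target was called at an adjusted p under 0.05 and a log2 ratio of at least 0.5 either way. The peak of the female-higher class was the highest density above 0.5, with a bandwidth of 0.05 chosen during the work. With 3 arrays an exact sign-flip test of 1 value cannot give a two-sided p below 0.25, so calls rest on the model over all targets. On simulated targets with the arrays' own spread (13012 targets, 200 of them changed), the fit for the female over male comparison recovered 94.0% of targets changed by 0.85, 78.0% of those changed by 0.6, 94.0% of those changed by -0.85 and 100% of those changed by -3, each over 50 targets, with 1 false call. The simulation changed far fewer targets than were called on the arrays, as many up as down. It had independent noise and no dye effect, so these rates need not hold for the arrays.

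The tests, thresholds, the rule for named targets and all alternatives but the last one listed below were fixed before the data were examined. The rule was that, where the files give no gene names, at most 2 female-higher and 2 male-higher targets are named, those with the largest ratios past the threshold. Tests of Drosophila chromosome arms (6 lists) and of functional groups (6 lists) had been planned; the gene name column repeats the probe ID on every probe spot, 0 of 443 listed symbols matched, and these tests were not run. The comparisons of ID types and of target numbers were added after the ratios were seen. Stretches of target numbers were found by splitting the ordered female-higher calls wherever a binomial log likelihood gained more than 25, with at least 50 targets on each side, settings chosen after the ratios were seen. Targets were treated as sharing sequence if their probes had a stretch of 25 bases in common on either strand, which joined 14039 targets into 12630 groups. Alternatives were normexp background correction (offset 50), the scanner's uncentred ratio, within-array loess, the value table, centring on the mode, other filters on dim and saturated spots, a dye term, a correction for probe GC content, other ratio thresholds, the median over probes, 1 probe per target, leaving out each array, and, added later, 1 target per group sharing sequence. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for exact tests, intervals and figures.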

Results

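Genomic DNA of female and male Teleopsis quinqueguttata, a stalk-eyed fly of the family Diopsidae, was compared by array comparative genomic hybridization, in which female and male DNA carry different fluorescent dyes and compete for the same probes. Each of the 3 arrays, labelled replicates 1, 3 and 4, held a separate pair of a female and a male pool of 4 or 5 adult flies taken from cages founded with flies from Gombak in Malaysia. Female DNA carried Cy3 on replicates 1 and 3 and Cy5 on replicate 4, so replicate 4 had the dyes exchanged. The array held 75082 probes of 60 bases, each printed on 2 spots, for 14039 targets whose IDs begin with Ass12. The files pair these IDs with no gene name, organism or genome position, so targets are reported by ID. The study's title names the position of the sex chromosome and the movement of genes as its subject. A sequence present in 2 copies in females and 1 copy in males has a theoretical log2 female over male ratio of 1, and a sequence present in equal copy number has a ratio of 0.

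Signals were well above background for 98.5% or more of probe spots in the female channel and 97.9% or more in the male channel on every array, and no probe spot was saturated. The 2 spots of a probe gave closely similar log2 ratios, with Pearson's r across probes of 0.990, 0.982 and 0.982 on replicates 1, 3 and 4. After averaging over the probes of a target, log2 ratios of different arrays correlated across targets with r = 0.956 for replicates 1 and 3, r = 0.916 for replicates 1 and 4 and r = 0.923 for replicates 3 and 4. Targets are not independent replicates, and these values describe the arrays only. All 3 correlations were positive once ratios were turned to female over male, including both that set replicate 4 against an array of the other dye orientation. The median SD over the 3 arrays was 0.079 on the log2 scale for a target, and the number of arrays limits the precision.

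Most targets had a ratio near 0 or fell into a well separated female-higher class, and a smaller set, less clearly set apart, had the stronger signal from male DNA. Of 13012 targets with at least 3 retained probes, 10389 (79.8%) had a mean log2 ratio within 0.25 of 0. A further 2258 targets (17.4%) were higher in females and 223 (1.71%) were higher in males, by limma's moderated test with a Benjamini-Hochberg adjusted p under 0.05 and a log2 ratio of at least 0.5 either way. On the female side the region between the classes was nearly empty, since 23 targets had a mean log2 ratio from 0.25 to 0.5. On the male side 117 targets lay from -0.5 to -0.25, and the male-higher count depended on the minimum ratio: with none, 368 targets were male-higher and 2292 were female-higher. Each of the 2258 female-higher targets had a ratio above 0 on 3 of 3 arrays, and 2130 of them exceeded 0.5 on 3 of 3 arrays. Each of the 223 male-higher targets was below 0 on 3 of 3 arrays, and 185 were below -0.5 on 3 of 3. The calls were made from these same arrays, so these counts are not independent support for them. At the level of single probes, 11883 of 74198 (16.0%) were higher in females and 1308 (1.76%) were higher in males by the same test.

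**Figure D1:**
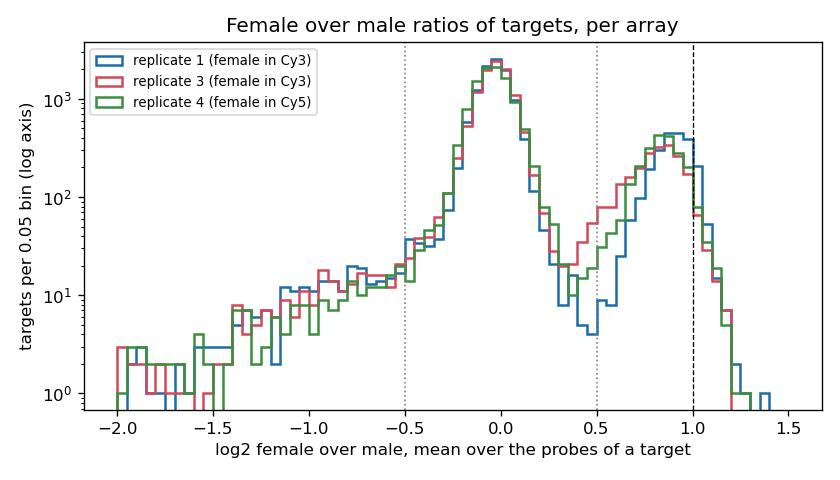
Histograms of log2 female over male ratio (x axis) for the 13012 targets, with the number of targets per 0.05 bin on a log axis, 1 line per array; dotted lines mark -0.5 and 0.5, the dashed line marks the theoretical ratio of 1, and the 33 targets below -2 on any array run off the left edge. On each array a second peak stands between 0.84 and 0.91, apart from the main peak near 0.

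The female-higher class formed a narrow peak somewhat below the theoretical ratio for 2 copies against 1. Its highest density lay at a log2 ratio of 0.91 on replicate 1, 0.85 on replicate 3 and 0.84 on replicate 4, or 0.87 ± 0.04 (SD, n = 3). The main peak lay at -0.03 ± 0.01 (SD, n = 3), so that the 2 peaks were 0.90 ± 0.04 (SD, n = 3) apart on the log2 scale. The share of targets above 0.5 was 17.4%, 16.5% and 17.4% on replicates 1, 3 and 4, or 17.1% ± 0.535 (SD, n = 3). The middle 50% of female-higher targets had mean ratios from 0.79 to 0.90 with a median of 0.85, a 1.81-fold difference, and the highest reached 1.08. Probes within a target mostly moved together: every retained probe was above 0 in 2212 of the 2258 female-higher targets and above 0.5 in 1633.

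The 2 highest female-higher targets were Ass12_CDS_4032 and Ass12_17719. Ass12_CDS_4032 had a log2 female over male ratio of 1.08 ± 0.12 (SD, n = 3), with a standard error of 0.057 and an adjusted p of 2.55e-06 by limma. All 6 of its probes were higher in females. Its probe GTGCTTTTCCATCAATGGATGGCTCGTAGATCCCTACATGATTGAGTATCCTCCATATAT gave 1.06 ± 0.09 (SD, n = 3). Ass12_17719 had a ratio of 1.04 ± 0.15 (SD, n = 3), with a standard error of 0.063 and an adjusted p of 3.06e-06 by limma. Its probe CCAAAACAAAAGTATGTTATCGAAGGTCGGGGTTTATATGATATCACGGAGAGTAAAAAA gave 0.99 ± 0.01 (SD, n = 3). The 6 probes of Ass12_17719 gave means from 0.92 to 1.19, with SDs over arrays from 0.01 to 0.32. Probes of Ass12_17719 shared sequence with 1 other target.

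The male-higher class ran from the threshold down to a log2 ratio of -6.01. Its median was -0.91, equal to a 1.88-fold stronger signal in males. Of the 223 targets, 98 were at or below -1 and 21 were at or below -3, which is at least 8-fold stronger in males. All 223 had at least 1 probe well above background in the female channel on 3 of 3 arrays, and in 201 of them every retained probe was. Among the 21 strongest this held for every retained probe in 17, and the folds of the other 4 include female signals not well above background. Every retained probe was below 0 in 219 of the 223 targets and below -0.5 in 165.

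The 2 lowest targets were Ass12_14712 and Ass12_CDS_4851, with male signals 64.2-fold and 58.2-fold above female signals. Every retained probe of both was well above background in the female channel on 3 of 3 arrays. Ass12_14712 had a log2 female over male ratio of -6.01 ± 0.20 (SD, n = 3), with a standard error of 0.074 and an adjusted p of 6.80e-09 by limma. Its probe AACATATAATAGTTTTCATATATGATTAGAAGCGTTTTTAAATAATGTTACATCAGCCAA gave -6.64 ± 0.21 (SD, n = 3), and its probes shared sequence with 1 other target. The 4 probes of Ass12_14712 gave means from -6.64 to -5.65. Ass12_CDS_4851 had a ratio of -5.86 ± 0.57 (SD, n = 3), with a standard error of 0.17 and an adjusted p of 5.41e-07 by limma. Its values were -6.36 on replicate 1, -6.00 on replicate 3 and -5.24 on replicate 4. Its 5 probes gave means from -6.00 to -5.57. Its probe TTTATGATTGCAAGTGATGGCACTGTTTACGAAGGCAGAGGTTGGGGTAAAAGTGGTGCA gave -5.57 ± 0.59 (SD, n = 3).

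**Figure D2:**
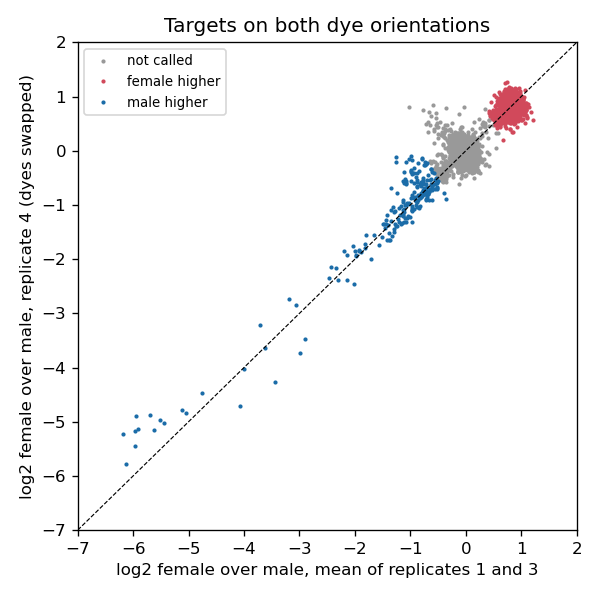
Each point is 1 of the 13012 targets, with the mean log2 female over male ratio of replicates 1 and 3 on the x axis and the ratio of replicate 4, with dyes exchanged, on the y axis; the dashed line marks equality and colours mark the calls. The 2258 female-higher targets form 1 cloud near 0.85 on both axes, and the 223 male-higher targets reach down to -6, with 34 of them more than 0.5 from equality.

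Because female DNA carried Cy3 on 2 arrays and Cy5 on 1, part of any dye effect stayed in the mean ratio. Replicate 4 differed from the mean of replicates 1 and 3 by more than 0.5 on the log2 scale for 113 targets, of which 74 were in neither class, 34 were male-higher and 5 were female-higher.

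The proportion of both classes differed between the 2 kinds of target ID, a split chosen after the values were seen. Female-higher targets made up 17.6% of the 11930 targets with CDS in the ID and 14.1% of the 1082 others (Fisher's exact test, two-sided p = 0.0033, Benjamini-Hochberg adjusted over 2 tests 0.0033). The higher CDS share rested on 1 stretch of numbers, 5484 to 6829, described below. Outside it, with 1 target per group sharing sequence, 11.8% of 9774 CDS targets were female-higher. That is below the share of the other IDs, which were not reduced in this way. Male-higher targets made up 1.40% of CDS targets and 5.18% of the others (two-sided Fisher's exact p = 2.56e-14, adjusted 5.11e-14). Replicate 4, with exchanged dyes, stood apart here: 20 of the 56 male-higher targets without CDS in the ID fell short of -0.5 on it, against 1 on replicate 1 and 1 on replicate 3, and the 36 that did not made up 3.33% of such targets. Of the 167 male-higher CDS targets 10 fell short on replicate 4, and the 157 that did not made up 1.32%. Targets that share sequence are not independent, so these p-values are too small. Many of the 56 male-higher targets without CDS had IDs in 1 run, from Ass12_13262 to Ass12_13491. Their excess therefore need not be a trait of the ID type. Clustering along the IDs without CDS was not tested.

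The female-higher CDS targets were unevenly spread over the numbers in the target IDs, which the files do not explain and which were examined only after the ratios had been seen. Numbers 5484 to 6829 held 1098 tested targets, of which 822 (74.9%, exact 95% binomial interval 72.2 to 77.4) were female-higher. This stretch held 39.0% of all female-higher CDS targets. The neighbouring numbers 4338 to 5483 had 41 female-higher targets of 986 (4.16%, interval 3.00 to 5.60), and numbers 6830 to 11505 had 145 of 3939 (3.68%, interval 3.11 to 4.32). The first stretch, 1 to 4337, had 20.3% (interval 18.9 to 21.6) and the last, 11506 to 14889, had 16.3% (interval 14.8 to 17.8). The intervals cover counting error only. Male-higher targets made up from 0.93% of the last stretch to 3.14% of numbers 4338 to 5483.

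**Figure D3:**
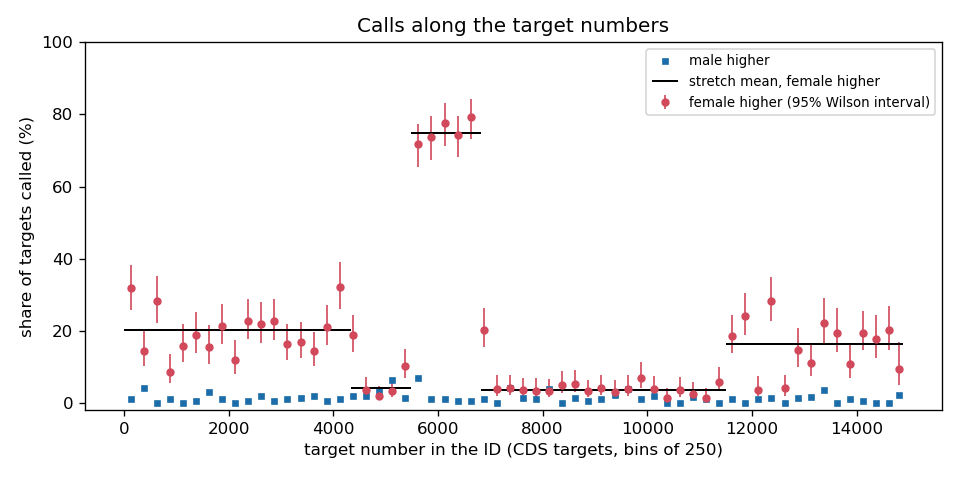
Share of CDS targets called female higher (circles, with 95% Wilson intervals) and male higher (squares) in bins of 250 target numbers along the x axis; horizontal lines give the female-higher share of each of 5 stretches. The stretch from 5484 to 6829 stands at 74.9%, between neighbours at 4.16% and 3.68%.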

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

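The 4 counts of female-higher and male-higher targets and probes kept their direction and stayed within 1.5 times the reported count under the alternatives run, with 1 exception: with no minimum log2 ratio, 368 targets were male-higher in place of 223, because smaller ratios were then admitted. The range over alternatives that kept all arrays was 2036 to 2416 female-higher targets, and its ends come from keeping 1 target per group sharing sequence (chosen after seeing the data) and from testing targets with 1 probe. These 2 settings tested 11709 and 14036 targets in place of 13012. Their female-higher shares were 17.4% and 17.2%, against 17.4% in the reported fit. Leaving out each array in turn gave 2229 to 2265 female-higher targets, 222 to 255 male-higher targets and a peak from 0.85 to 0.88. The peak of the female-higher class moved by more than its SD over arrays when raw signals were corrected by normexp (0.94) and when arrays were centred on the mode (0.91); the cause of the first was not tested, and the second removes the pull of the female-higher targets on the median. With a dye term, 2257 targets were female-higher, 2256 of them shared with the fit without it, and 216 were male-higher, 215 of them shared. The 4 named targets stayed past the threshold in every alternative that measured them. Signal over background limited little, since asking for both channels above background kept 73572 of 74198 probes and gave 2249 female-higher targets. Leaving out saturated spots removed no probe and says nothing about stability. The value table gave 2169 female-higher targets, 2164 of them shared with the scanner values, as 19.1% of 11341 targets in place of 17.4%. The comparison was already paired, since each array held a female and a male pool and the ratio within the array was tested. The arrays form a single group, so no further pairing was available. The tests of chromosome arms and of gene lists were not run, under any alternative, for lack of gene names.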

Other observations

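The tests of chance order, residual background, centring, dye and repeated counting of male-higher targets, and the sign flips, were chosen after the results they test had been seen; those of near-identical neighbours and of slide position were written before their own outcomes, but after the patterns they bear on had been seen. The dye test replaced one on the 223 targets called from all arrays, which replicate 4 had helped to call.

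Within the stretch of target numbers 5484 to 6829, the 276 targets that were not female-higher mostly had no sex difference, since 239 had a mean log2 ratio within 0.25 of 0. After keeping 1 target per group sharing sequence, 248 of 998 targets in the stretch were not female-higher. In the ordered list of kept targets, where numbers not kept were skipped, they formed 118 adjacent pairs. The 10000 shuffled orders gave 61.4 on average and 85 at most (one-sided permutation p = 0.0001, the smallest these shuffles can give). The 1283 female-higher CDS targets outside the stretch had nearly the same ratio as the 822 inside: the median log2 ratio was 0.85 ± 0.05 outside and 0.86 ± 0.05 inside (SD, n = 3). The difference was 0.013 ± 0.010 (SD, n = 3), above 0 on 3 of 3 arrays.

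Some targets were divided. In 18 targets at least 2 probes had a mean log2 ratio above 0.5 while at least 2 others lay within 0.25 of 0, and in 17 targets at least 2 probes were below -0.5 while at least 2 others lay within 0.25 of 0. What sets these targets apart was not tested.

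The concentration of female-higher targets in 1 stretch of numbers was set against 3 technical explanations. The highest share over 500 consecutive CDS targets was 77.4%, against at most 26.8% in 10000 shuffled orders (one-sided permutation p = 0.0001, the smallest these shuffles can give), which argues against a chance order. Neighbouring targets whose probes share sequence do not account for it. With 1 target per group sharing sequence, 75.2% (exact 95% binomial interval 72.3 to 77.8) of the stretch was female-higher, against 11.8% outside. This kept 998 of the 1098 tested targets in the stretch, so sharing was too rare to move the share far. The bounds of the stretch were drawn from these same calls, so the contrast and its interval are not independent support. Only probe sequences were compared, so near-identical targets with probes at different positions were not joined and are not excluded. Position along the spot rows of the slide does not account for the concentration either. The lowest share of the stretch's probe spots above 0.5 over 10 bands of spot rows was 66.7%, against at most 11.8% for other CDS probes. Position along the spot columns was not tested. A candidate explanation is that the numbers follow a chromosomal order in part of the list, so that the stretch is largely 1 chromosome carried in more copies by females; the files give no position to test this.

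The position of the female-higher peak below 1 was weighed against 2 technical explanations. Median centring lowers it only in part, since with centring on the mode it lay at 0.9128, still below 1 by more than the SD over arrays of 0.037. Residual background, which would lower the ratios of dim probes most, cannot be told apart from other sources: with probes of female-higher targets ranked by brightness into 4 equal sets, the median log2 ratio of the dimmest set exceeded that of the brightest by 0.041 ± 0.10 (SD, n = 3), and the sign differed between arrays. A normexp background correction of the raw signals moved the peak further than the mode did, to 0.9378. It also left out the deposited detrend and dye normalization, so this move cannot be put down to background alone. No biological explanation was tested.

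Of 255 targets called male-higher from replicates 1 and 3 alone, 237 (92.9%) were below 0 on replicate 4 with exchanged dyes and 190 were at or below -0.5 there, with a median log2 ratio of -0.79, while of 2249 targets so called female-higher, 2249 were above 0 and 2229 were at or above 0.5 there. A dye effect behind the whole class would turn the sign on replicate 4 and is excluded by that median, but the 92.9% missed a bound of 95% set after the first results, and dye and fly pool cannot be told apart for the 65 male-higher targets that fell short of -0.5 there, 18 of them above 0. Repeated counting of targets whose probes share sequence does not account for the class. With 1 target kept per group sharing sequence, 192 were called male-higher, though near-identical targets with probes at different positions were not joined. Among the CDS targets so kept, 144 were male-higher. In the ordered list of kept targets, where numbers not kept were skipped, 45 adjacent pairs were both male-higher. The 10000 shuffled orders gave 1.92 on average and 9 at most (one-sided permutation p = 0.0001, the smallest these shuffles can give). Whether the male-higher targets lie on a male-limited chromosome, in repeats that differ between the sexes or in DNA of another organism carried by males was not tested.

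The 3 arrays allow 4 sign patterns, too few for a share under 0.05. The real pattern gave 2481 targets past the threshold and was the 1 pattern with as many; the highest of the other patterns gave 0. Turning the sign of 1 array sets it against the other arrays at the called targets. The low counts therefore follow from the correlations between arrays and are no further support.

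Replicate 4 lay more than 0.5 from the mean of replicates 1 and 3 for 113 targets, above it in 88 and below it in 25, while replicate 3 lay that far from replicate 1 for 60. With 1 array of the exchanged orientation, dye and pool were confounded.

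The deposited value table ends within the alphabetical list of probes, and the 1649 tested targets it leaves out held 85 female-higher targets, or 5.15%, against 19.1% of the 11363 targets with at least 1 probe in it. A share of female-higher targets taken from the table alone is therefore higher than the 17.4% of the whole array.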
